A study of Drosophila melanogaster with 3 samples.

How the data were processed

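Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map the genome occupancy of Sox15 in whole Drosophila melanogaster prepupae, the stage between larva and pupa. The flies carried a Sox15 transgene fused to enhanced green fluorescent protein (eGFP), and the tagged protein was pulled down with an antibody against GFP, per the labels. Sexes were pooled, and sonication gave fragments of 200 to 800 bp, per the labels. The series has 1 group of 3 biological replicates. It therefore holds no contrast between conditions, and the comparisons made were of replicates with each other and of the occupied positions with the rest of the genome. The listing that came with the files names a control file among the inputs of the replicate and pooled peak lists, but no control library was analysed here.

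The deposited files are peak lists, each given in coordinates of the dm6 and of the dm3 assembly. For each replicate there is a relaxed list, which by its name holds peaks and background prepared for an irreproducible discovery rate (IDR) analysis. The series also has a relaxed list from the pooled replicates and an optimal IDR set. The aligner and the peak caller are not given in the sources used here. Each deposited peak has a signal value, whose scale is not stated and which was used only to rank and describe peaks within 1 list. Each deposited peak also has a −log10 q-value, while the p-value column is filled with a placeholder throughout. The 4555 deposited IDR peaks of dm6 were the 4555 pooled peaks of highest signal, so the set was treated as a threshold on the pooled list. Read counts were not given in the sources used here, so the depth of each library is unknown, and the precision is limited by the number of libraries and peaks. Intervals on shares are 95% Wilson intervals and cover counting error only.

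All positions are dm6 coordinates unless stated, and dm3 coordinates were never converted. Genes came from an Ensembl annotation of the BDGP6 assembly and sequence from the RefSeq Release 6 assembly, whose arm names and lengths fit the dm6 lists. All dm6 peaks lay on the 6 arms 2L, 2R, 3L, 3R, 4 and X. The position of a peak was its deposited summit.

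The main settings were fixed before the data were examined. An IDR peak was matched to a replicate when a peak among the 4555 highest-signal peaks of that replicate covered at least 50% of its length. The overlap expected by chance came from 100 random placements of the replicate peaks on their arms. A promoter was the 500 bp to either side of any annotated transcription start site. Its share was tested against 10000 random placements of the summits on the same arm (two-sided). The remaining positions were assigned in the order 5' UTR, coding exon, 3' UTR, non-coding exon, intron and intergenic. Sequence patterns, 18 in number, were sought on both strands within 100 bp of the summit. Each was compared with a window of the same size 1000 bp away on a randomly chosen side by the exact McNemar test. All 6-base words found at 100 or more summits were ranked by their odds at summits over flanks. A protein-coding gene was called occupied when an IDR summit lay within 1000 bp of one of its start sites. The 20 gene lists were compared with all other protein-coding genes by Fisher's exact test (two-sided). As an alternative, 10000 random lists matched on gene length decile and number of start sites were drawn. Arms were tested by the exact binomial test against their share of the length and, as an alternative added later, by rotating bins of 100 kb along the arms, and trends over quartiles of signal by 100000 permutations. The p-values of the patterns, gene lists, gene families, arms, signal trends and replicate-only peaks were adjusted within their family by the Benjamini-Hochberg method, with a threshold of 0.05. All other p-values, including those of the first intron, nearest start site, word and orientation tests in the closing section, are unadjusted.

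The genes named in the text followed a rule set in advance. It took Sox15, the 20 genes nearest to the strongest summits within 1000 bp of a start site, up to 4 occupied members of each list by signal, and the 5 strongest peaks by position. Of the symbols written in the lists, 2 testis, 1 ribosomal protein and 5 histone symbols had no single match in the annotation and were left out. A few older symbols were replaced by current ones before the values of the lists were examined. The side of the start site on which promoter summits lay and the profiles of GC content and coding sequence around summits were added after the main results had been seen. The 12 gene families in the closing section were defined by symbol after the lists had been seen.

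In simulated data, peak matching recovered 100% of 2705 peaks shifted by a small amount among 4555, and also matched 50 of the remaining peaks, which had been moved by 20 kb. In the same way, the motif test called 20 of 20 planted patterns and 0 of 20 others at an unadjusted p under 0.05. The Fisher test recovered 95% of 100 simulated lists of 40 genes with occupancy raised 2.5-fold, and called 1 of 100 unchanged lists. Alternatives covered the overlap rule, the number of peaks, the promoter and motif windows, control windows, the gene assignment, the stricter part of the IDR set (the 2277 peaks of highest signal), the dm3 files and leaving out each replicate. For promoters, patterns and genes, leaving out a replicate meant keeping the IDR peaks matched in both others, which also adds a filter, since the pool could not be remade. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.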

Results

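Genome occupancy of Sox15 was measured in whole prepupae carrying an eGFP-tagged copy of the protein. Sox15 is a transcription factor of the Sox family, whose members bind DNA through a high-mobility-group (HMG) domain. The 3 biological replicates had relaxed peak lists of 19304, 19033 and 16102 peaks. Pooling of the replicates had given 14164 peaks, and the reproducible IDR set held 4555 peaks with a median signal of 205.2 and a median width of 396 bp. The signal values given here are those of the authors' peak lists.

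The tagged locus was examined first. Sox15 (FBgn0005613, 2R, 14201390 to 14212413, minus strand) contained 0 IDR summits. The pooled list held 3 weak peaks inside the gene, with signals of 69.4, 50.6 and 47.7, against a minimum of 116.6 in the IDR set. Stronger pooled peaks, also below that minimum, lay upstream, 2053 and 2568 bp from the start site, with signals of 94.95 and 96.04. The nearest IDR peak (2R, 14216413 to 14216808) lay 4198 bp from the Sox15 start site, in the promoter of the ribosomal protein gene RpS23, with a signal of 213.8 and rank 2143.

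The 5 strongest peaks, of which 2 lay in promoters, 2 in introns and 1 in intergenic sequence, were matched in all 3 replicates. The strongest peak (3L, 19590439 to 19590807, signal 3852) lay in the promoter of CG14100, 97 bp from its start site, and ranked 1 in each replicate. The next (2L, 480901 to 481280, signal 3325) lay in an intron of ush, which encodes a GATA cofactor, 1412 bp from the start site of cbt. The third lay in an intron at HmgZ and HmgD, genes of HMG-box chromatin proteins (2R, 21703177 to 21703670, signal 3080). The fourth lay in the promoter of Ugalt, a UDP-galactose transporter gene (X, 2703709 to 2704065, signal 2974). The fifth was intergenic (2R, 13035161 to 13035500, signal 2631), 11918 bp from the nearest protein-coding start site, that of CG13323. Each of these 5 peaks ranked 7 or better in every replicate.

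Further down the ranking, the genes nearest to the strongest summits had varied functions, and no theme was tested among them. Chro, which encodes the chromodomain protein Chromator, had a signal of 2618, and the Polycomb group gene ph-p had 1994. The transcription factor gene Adf1 had 1957 in an intron. Among genes linked to translation, eIF6 had 2018, larp 1977, the mitochondrial ribosomal protein gene mRpL41 2096 and the kinase gene Lk6 2206. PNPase, which encodes a polynucleotide phosphorylase, had 2419, and the arginine methyltransferase gene Art3 had 2332. The adaptor gene Shc had 2058 and CenG1A had 1908. Tcs5, CG4496, CG8320, CG31145, CG5098 and CG1888 completed the 20 strongest genes, with signals of 1896 to 2582. The summits of the 20 genes lay 41 to 966 bp from a start site, and each of the peaks was matched in the top 4555 peaks of all 3 replicates.

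How far the replicates shared the IDR peaks was then compared. In the top 4555 peaks of each replicate, 92.1% of IDR peaks were matched in replicate 1, 89.3% in replicate 2 and 86.0% in replicate 3. The match to all 3 replicates was 73.4% (95% interval 72.1 to 74.7%), and 3345 peaks made up this set. Random placement gave 0.00022%, but the IDR peaks came from the pool of the same replicates, so overlap is built in and this is not a test of reproducibility. These peaks had a median signal of 243.1, against 138.5 for the 944 peaks matched in 2 replicates and 124.3 for the 261 matched in 1, an order largely set by the rule, since a match needs a high signal in the replicate. The share at promoters was 41.3%, 40.9% and 42.1% in these sets. Between pairs of replicates, 84.9% of the top peaks overlapped for replicates 1 and 2, 81.6% for 1 and 3, and 81.3% for 2 and 3, a mean of 82.6% ± 2.0 (SD, n = 3 pairs). Spearman's rho of the signal across IDR peaks was 0.839, 0.808 and 0.814 for these pairs. It was computed across peaks that had been selected for high signal, and peaks are not independent replicates. The matched share rested on the overlap rule, falling to 22.8% when 90% of the peak length had to overlap.

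Few top peaks belonged to 1 replicate only. Replicate 1 had 10 such peaks, replicate 2 had 5 and replicate 3 had 18, with no overlapping peak in the relaxed lists of the other replicates. Their median signals in replicates 1, 2 and 3 were 62.0, 34.9 and 28.8, against 121.0, 65.2 and 52.8 for shared peaks. The tests of promoter share did not allow for this difference in signal. In replicate 3, 11.1% of the replicate-only peaks lay in promoters, against 41.6% of the 3075 peaks shared by all replicates (Fisher's exact test, p = 0.00774, adjusted p = 0.0464). In replicate 1, 80% lay in promoters, against 41.3% (exact p = 0.0203, adjusted p = 0.0608). The share in replicate 2 was 40%, against 42.4% (exact p = 1).

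Summits were concentrated at promoters and almost absent from coding exons. Of the 4555 summits, 1881 (41.3%, 95% interval 39.9 to 42.7%) lay within 500 bp of a start site, where 13.5% ± 0.51 (SD over placements) were expected from random placement. The authors' peak lists are recorded as made with a control file. Its reads were not analysed here, so any background at promoters that it left is not separated from occupancy by the tagged protein in this share. This 3.05-fold excess had a permutation p = 0.0001, the smallest that 10000 placements can give. Random shifts of each summit by 10 to 50 kb, which keep it in its region, gave a higher expected share of 16.7%, so the excess over nearby sequence was smaller. Introns held 1856 summits (40.7%, expected 39.5%), and intergenic sequence held 738 (16.2%, expected 27.3%). Coding exons outside promoters held 6 summits (0.132%, 95% interval 0.0604 to 0.287%), where 13.7% were expected. The 3' UTRs held 18 summits (0.395%, expected 4.43%). The median distance to a start site was 893 bp. Of the promoter summits, 83.6% lay upstream of the nearest start site (95% interval 81.9 to 85.2%).

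**Figure D1:**
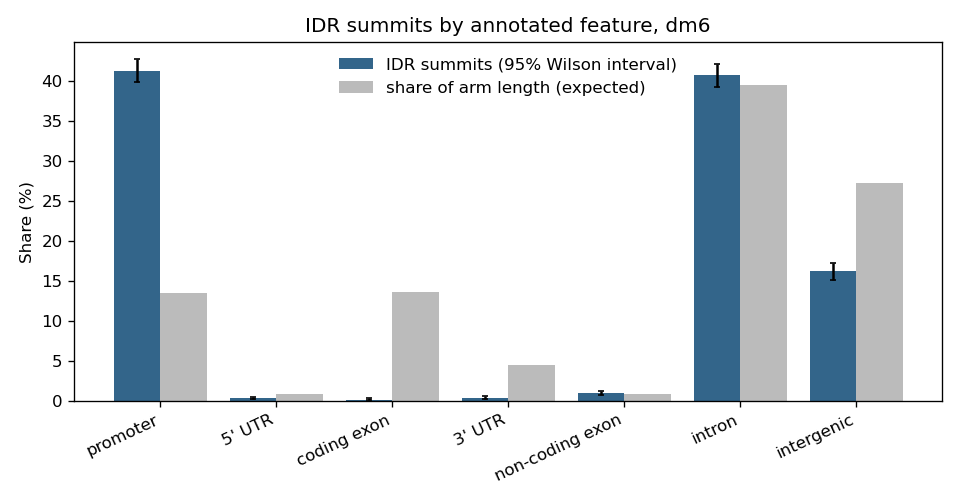
Share of the 4555 IDR summits (blue bars, %) by annotated feature in dm6, with 95% Wilson intervals as error bars, beside the share of arm length in each feature (grey bars, %). Promoters held 41.3% of summits against 13.5% of the length, and coding exons 0.132% against 13.7%.

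Stronger peaks lay more often at promoters. The share was 50.2% in the quartile of IDR peaks with the highest signal, then 41.3%, 37.6% and 36.1% in the following quartiles (permutation p of the trend 1e-05, the smallest that 100000 permutations can give, adjusted p = 0.00019). The Sox core pattern was found at 25.9% of summits in the strongest quartile and 23.6% in the weakest (permutation p = 0.198, adjusted p = 0.469). Of the 18 patterns, 0 showed a trend after adjustment. The lowest unadjusted p among the patterns was 0.0643, for Motif 1.

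The base composition at summits differed from that of the flanks. The mean GC content within 100 bp of the summit was 34.2%, against 42.5% at 1000 bp. In narrower windows, reaching 25 bp to each side, it was 31.5% at the summit. At 200 bp on either side it was 43.7% and 44.2%, against a mean of 42.2% over the arms. Coding sequence made up 0.373% of positions at the summit, including promoters, and 18.5% and 18.8% at 1000 bp to either side, against 17.1% over the arms.

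**Figure D2:**
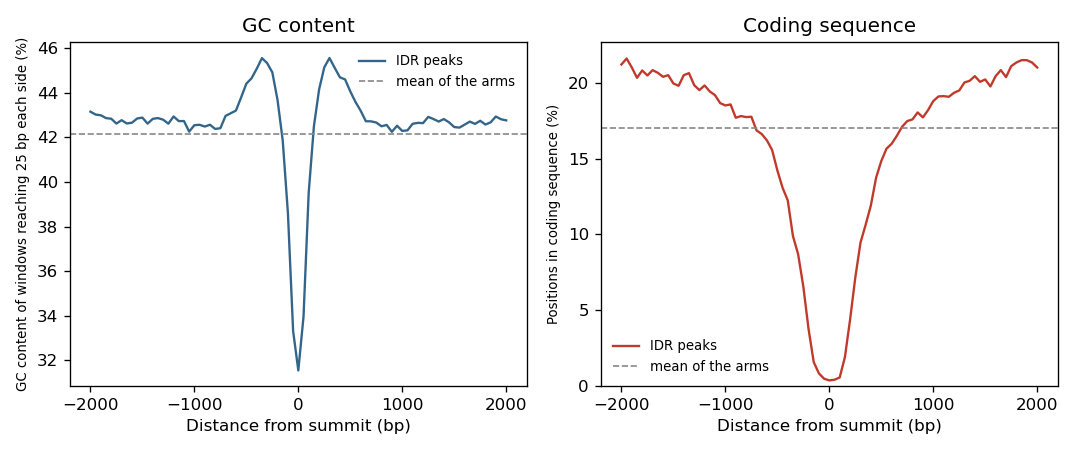
GC content (left, % in windows reaching 25 bp to each side) and share of positions in coding sequence (right, %) by distance from the IDR summit in bp, as lines over the 4555 peaks, with the mean of the arms dashed. GC content was lowest at the summit, at 31.5%, and coding sequence made up 0.373% of positions there.

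The core sequence known for Sox proteins was more frequent at summits than 1000 bp away, by a small margin. AACAAT was found near 24.6% of summits and in 20.1% of flanking windows, a 1.22-fold difference (exact McNemar test, p = 3.71e-08, adjusted p = 1.11e-07). It was present only at the summit for 904 peaks and only in the flank for 684. The shorter ACAAT gave 51.3% against 43.1% (exact McNemar test, adjusted p = 1.23e-14). The related pattern ACAAAG, shared with TCF factors, gave 13.2% against 14.5% (exact p = 0.0547, adjusted p = 0.0657). Among the 30 words with the same bases as AACAAT, its ratio ranked 28, and against that control its value lay below the median of the others. Among all 1917 ranked words it ranked 418.

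Several other patterns had larger ratios over the flanks, whose GC content is higher, given here from the lowest adjusted p. The TATA box pattern was found near 18.05% of summits and in 8.83% of flanks (2.04-fold, exact McNemar test, adjusted p = 7.03e-38), with 2.85-fold in promoters and 1.66-fold elsewhere. It was followed by the homeodomain core TAATTA, near 19.3% and in 12.1% (1.59-fold, exact test, adjusted p = 2.02e-20), with 2.31-fold and 1.28-fold. The DNA replication-related element (DRE), TATCGATA, which marks promoters of housekeeping genes, was found near 1.95% and in 0.395% (4.94-fold, exact test, adjusted p = 1.52e-15). In promoters its ratio was 16-fold (exact test, adjusted p = 1.08e-17), and at the other summits 0.692-fold (adjusted p = 0.591). Motif 1, another core promoter element, gave 3.44-fold (exact test, adjusted p = 1.47e-07), with 7.56-fold in promoters and 1.13-fold elsewhere (adjusted p = 0.862). The difference between promoters and other summits was not tested, and the flanks were not matched on promoter status. The GATA pattern AGATAA gave 1.28-fold (exact test, adjusted p = 5.72e-06). In all, 8 of the 18 patterns were more frequent at summits and 5 less frequent. Windows of 50 bp gave 7 and 6, and windows of 250 bp gave 8 and 2. Against windows elsewhere matched on GC content and promoter status, 5 were more frequent and 3 less (1000 draws, permutation). Lower at summits were CA repeats (0.433-fold, exact McNemar test, adjusted p = 2.74e-11), GAGA repeats (0.572-fold, adjusted p = 4.94e-06), the proneural E-box CAGCTG (0.768-fold, adjusted p = 0.000445), the nuclear receptor site AGGTCA (0.759-fold, adjusted p = 0.00157) and the Grh site (0.424-fold, adjusted p = 0.0265). The Su(H) site, bound by the effector of Notch signalling, gave 0.786-fold (exact test, adjusted p = 0.0685).

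Most of these calls changed with the GC-matched windows, a control chosen after the flank results had been seen. The TATA box (1.05-fold, permutation, adjusted p = 0.194), TAATTA (1.02-fold, adjusted p = 0.608), AGATAA (0.997-fold, adjusted p = 0.947) and the DRE core ATCGAT (1.05-fold, adjusted p = 0.45) were no longer called. The DRE (1.74-fold, permutation, adjusted p = 0.0036) and Motif 1 (2.17-fold, adjusted p = 0.0036) stayed above, with smaller ratios. GAGA repeats (1.43-fold, permutation, adjusted p = 0.0036) and CAGCTG (1.45-fold, adjusted p = 0.0036) changed direction and lay above, as did the TAGteam site CAGGTAG (1.42-fold, adjusted p = 0.0405). CA repeats, AGGTCA and the Grh site were no longer called (permutation, adjusted p = 0.174, 0.224 and 0.608). AACAAT (0.926-fold, permutation, adjusted p = 0.00771), ACAAT (0.948-fold, adjusted p = 0.0036) and ACAAAG (0.888-fold, adjusted p = 0.00771) lay below.

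Occupied genes were counted next, and lists of genes fixed before the data were examined were compared with all others. Of 13968 protein-coding genes, 2694 (19.3%) had an IDR summit within 1000 bp of a start site. Of 20 lists, 6 differed from the other genes, 2 above and 4 below. Some lists shared genes, so their results are not independent. Of 39 wing hinge genes 13 were also in another list, as were 9 of 40 Hox and other homeobox genes. When each replicate was left out in turn, only IDR peaks matched in both other replicates were kept, 3572 to 3783 of the 4555, and 2 or 3 lists differed. The peaks still came from the pool of all replicates. The same filter with no replicate left out, on the 3345 peaks matched in all 3, gave 2 lists, so lost calls in these sets cannot be put down to the replicate left out.

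Genes of cytoplasmic ribosomal proteins were occupied most often. Of 80 such genes, 43 were occupied (53.8%, 95% interval 42.9 to 64.3%), against 19.1% of the others (2.82-fold, Fisher's exact test, p = 6.02e-12, adjusted p = 1.2e-10). RpS27 had a signal of 580.2, RpL32 529.7, RpS20 481.4 and RpL34b 456.2. All 4 summits lay within promoters, 29 to 166 bp from a start site. Among the 2277 IDR peaks of highest signal, taken as a stricter set, the ratio was 1.77-fold and the difference was lost (Fisher's exact test, adjusted p = 0.137).

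Genes of the response to ecdysone, the steroid hormone whose pulses start metamorphosis, were also occupied more often than others. Of 45 genes, 16 were occupied (35.6%, 95% interval 23.2 to 50.2%), against 19.2% (1.85-fold, exact p = 0.012, adjusted p = 0.0401). Sox14, an ecdysone-induced Sox gene, had the highest signal, 1653, in its promoter (2R, 23978411 to 23978735, rank 34). The cell death gene hid had 966.0, the transporter gene E23 790.4 and the lactate dehydrogenase gene Ldh 557.9. Against random lists matched on gene length and number of start sites the ratio was 1.32-fold and the difference was lost (permutation, adjusted p = 0.377). With gene bodies counted, the matched lists gave 1.42-fold (permutation, adjusted p = 0.0562). The difference was also lost within 500 bp (1.89-fold, Fisher's exact test, adjusted p = 0.0569). The same held in the stricter set (1.96-fold, exact test, adjusted p = 0.156), among peaks matched in all replicates (1.82-fold, adjusted p = 0.132), and in the filtered sets without replicate 1 (1.73-fold, adjusted p = 0.196) or 2 (1.69-fold, adjusted p = 0.176). In all, it was called in 3 of 10 alternative settings.

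The lists closest to the known roles of Sox15, in sensory bristles and the wing hinge, showed no excess of occupied genes in the main test. The chromatin came from whole prepupae, so occupancy limited to few cells could lie below the IDR threshold and was not assessed. Of 35 sensory organ genes, 8 were occupied (22.9%, 95% interval 12.1 to 39.0%, exact test, adjusted p = 0.811). These included numb, a Notch inhibitor in asymmetric division, with a signal of 805.4, elav with 749.8, brat with 523.4 and neur with 209.2. When a summit anywhere in the gene or 1000 bp upstream was counted, 15 of 35 were occupied (42.9% against 22.7%, exact test, adjusted p = 0.0222), a difference that length-matched lists did not show (1.17-fold, adjusted p = 0.56). Of 8 socket and shaft cell genes, 1 was occupied, the bristle actin-bundling gene sn (328.7). The 95% interval of this share, 2.24 to 47.1%, is too wide to show an excess or a lack. Of 39 wing hinge and patterning genes, 1 was occupied (2.56%, 95% interval 0.454 to 13.2%), less often than other genes (0.133-fold, exact p = 0.00383, adjusted p = 0.0191). That gene was Stat92E, with a signal of 455.8 in an intron. The difference was lost when summits in the gene body were counted (7 of 39, 0.788-fold, exact test, adjusted p = 0.813), in the stricter set (0.225-fold, adjusted p = 0.35), among peaks matched in all replicates (0.174-fold, adjusted p = 0.119) and in the filtered sets without replicate 1 (0.166-fold, adjusted p = 0.118), 2 (0.162-fold, adjusted p = 0.0768) or 3 (0.155-fold, adjusted p = 0.061). Against lists matched on gene length and number of start sites it held, at 0.0938-fold for start sites (permutation, adjusted p = 0.002) and 0.424-fold for gene bodies (adjusted p = 0.006).

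In the Notch pathway 12 of 32 genes were occupied (37.5%, 95% interval 22.9 to 54.7%, 1.95-fold, exact p = 0.0216), which missed the threshold after adjustment (adjusted p = 0.0616). It passed against lists matched on gene length and number of start sites (2.13-fold, permutation, adjusted p = 0.02). By the exact test it passed with gene bodies counted (1.93-fold, adjusted p = 0.0235) and within 5 kb (1.65-fold, adjusted p = 0.0187). It did not pass within 500 bp (1.51-fold, exact test, adjusted p = 0.422), in the stricter set (2.49-fold, adjusted p = 0.0755), among peaks matched in all replicates (1.70-fold, adjusted p = 0.318) or in the filtered sets without replicate 1 (1.62-fold, adjusted p = 0.352), 2 (1.98-fold, adjusted p = 0.086) or 3 (1.71-fold, adjusted p = 0.262). The corepressor gene gro had a signal of 914.8, E(spl)m3-HLH 657.5, the glycosyltransferase gene fng 640.7 and the gamma-secretase gene aph-1 497.9. Several occupied members were E(spl) genes, and E(spl)m3-HLH and gro lie close together on 3R, starting at 26021823 and 26041736. All of these list tests take such neighbours as independent genes, so they may overstate the evidence for this list. In the Wingless pathway 6 of 31 genes were occupied (19.4%, exact test, adjusted p = 1), with sgg, which encodes glycogen synthase kinase 3, at 839.9, CtBP at 307.9, dlp at 281.3 and nkd at 214.0. Counting gene bodies gave 16 of 31 (51.6%, exact test, adjusted p = 0.00213), and 1.43-fold over length-matched lists (adjusted p = 0.139). Of the 8 Sox genes, Sox14 and Sox102F (224.3) were occupied.

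Genes of gut, testis and chemosensory receptors were seldom occupied. Of 24 gut genes and 30 testis-specific genes, 0 were occupied, with Wilson upper limits of 13.8% and 11.4% (exact p = 0.0086 and 0.0038, adjusted p = 0.0344 and 0.0191). Of 79 odorant and gustatory receptor genes, 1 was occupied, Gr32a (0.0653-fold, exact p = 1.93e-06, adjusted p = 1.93e-05). The gut and testis differences were lost in the stricter set (exact test, adjusted p = 0.342 and 0.172) and among peaks matched in all replicates (0.132 and 0.112), with 0 genes occupied in each case. They were also lost in the filtered sets without replicate 1 (exact test, adjusted p = 0.164 and 0.0678), 2 (0.086 and 0.0675) or 3 (0.0803 and 0.0531), again with 0 occupied. Within 500 bp the gut difference was lost (exact test, adjusted p = 0.0804). Within 5 kb the testis genes had 0.615 times the share of other genes and the difference was lost (exact test, adjusted p = 0.218), while the gut genes had 0.11 times the share (adjusted p = 0.00142). The receptor difference held in all of these.

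Other cell type lists did not differ from all other genes in the main test. Of 25 neuron genes, 3 were occupied, namely Ank2 (779.5), elav (749.8) and Rbp9 (504.2), with an adjusted p = 0.757 from the exact test. Against length-matched lists the neuron genes were lower (permutation, adjusted p = 0.0243), as were Hox and other homeobox genes (3 of 40 occupied, adjusted p = 0.0212), which did not differ in the main test (adjusted p = 0.172). Of 27 muscle genes, 4 were occupied, with Zasp52 at 336.2 and sls at 259.1. Of 38 epidermis and cuticle genes 6 were occupied, with ds at 810.2, grh at 361.1 and Cht7 at 326.8, and of 19 trachea genes 4, with apt at 202.5. Fat body genes had 3 of 19, with bmm at 346.1, hemocyte genes 2 of 20, with PPO3 at 161.1, and salivary gland genes 1 of 17, CrebA at 329.5. Histone genes had 2 of 5, His2Av at 325.8 and His3.3B at 130.4. The adjusted p of these 7 lists, from muscle to histone genes, was 0.496 or higher in the main test. Within 5 kb, salivary gland genes (0.155-fold, exact test, adjusted p = 0.0187) and Hox and other homeobox genes (0.329-fold, adjusted p = 0.00255) were lower than other genes. With gene bodies counted, hemocyte genes were lower than matched lists (0.303-fold, permutation, adjusted p = 0.049), as were neuron genes (0.299-fold, adjusted p = 0.001). Hox and other homeobox genes did not differ with gene bodies counted, at 10 of 40 (1.10-fold, exact test, adjusted p = 0.832). Against matched lists they were at 0.629-fold (permutation, adjusted p = 0.116).

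**Figure D3:**
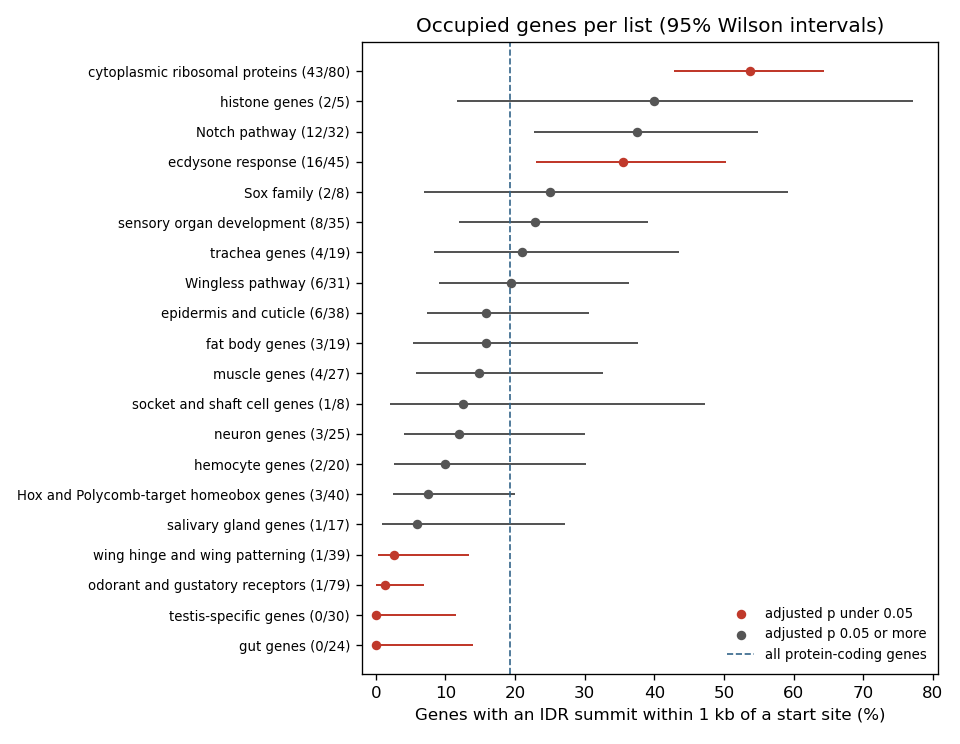
Share of genes with an IDR summit within 1000 bp of a start site (x axis, %) for the 20 lists, with 95% Wilson intervals as lines and occupied over total genes in parentheses. Red points had an adjusted p under 0.05, and the dashed line marks all protein-coding genes at 19.3%. Ribosomal protein genes were highest at 53.8%, while gut and testis genes were at 0.

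Peak density ranged from 30.96 to 36.6 per Mb on the large arms and was 7.42 per Mb on the small chromosome 4. The X had 36.6 IDR peaks per Mb, arm 3L 36.1, 2L 34.9, 3R 33.3 and 2R 30.96. The X (18.9% of peaks on 17.1% of the length, exact binomial test, p = 0.00154, adjusted p = 0.00359) and 3L (22.3% on 20.4%, p = 0.00258, adjusted p = 0.00451) had more peaks than their share of the length in a test that takes peaks as independent. Chromosome 4 had 10 peaks, 7.42 per Mb (exact p = 6.89e-10, adjusted p = 2.41e-09), and 1 of them lay in the promoter of Sox102F. The Y had 0 peaks, with an upper limit of 0.818 per Mb from a count of 0 (exact p = 6.01e-54, adjusted p = 4.2e-53). The binomial tests used assembled length, whether or not reads can be placed uniquely there. Peaks were clustered, with 354 of 1342 bins of 100 kb empty and up to 23 peaks in a bin. When bins were rotated along the arms, which keeps this clustering, 0 of the arms differed (1379 rotations, permutation, adjusted p = 0.983 for X and 3L, 0.751 for chromosome 4 and 0.147 for the Y). The Y alone had an unadjusted p under 0.05 (permutation p = 0.021).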

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

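Of the 4479 IDR peaks in the dm3 lists, 7 lay outside the main chromosome arms, on sequence the comparisons above did not use. They drew attention because a count of 0 would allow up to 3. The unplaced sequence named Uextra held 4 of them, and 2LHet, 3LHet and XHet, which are heterochromatic scaffolds, held 1 each. The dm6 lists had 0 peaks outside the main arms, and coordinates were not converted between the assemblies. The 3 replicates form a single group, which is too small for a test of outlying samples.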

How the results depend on the processing

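The GC-matched controls for the Sox core and the pattern list, the gene-body version of the matched random lists, the set of peaks matched in all replicates and the rotation of bins were chosen after seeing the data. Of 75 recomputed values, 48 kept their direction and call or stayed within a tolerance, 21 moved, 3 lost their call and 3 reversed. The tolerance was the spread, the Wilson interval for arm shares or, for counts, a fixed ratio to the main count. A count within it can hide changed calls. With gene bodies counted, 8 lists differed in place of 6, but the wing hinge list was no longer among them (exact test, adjusted p = 0.813). The shares of peaks on X (18.9%), 3L (22.3%) and chromosome 4 (0.22%) were no longer called when bins were rotated. The rotation allows for clustered peaks but had little power for the small chromosome 4. The share of IDR peaks matched in all replicates rose to 77.9% with 1 bp of overlap, 93.8% with the top 9110 peaks, 95.7% with whole lists and 94.99% in the stricter part of the IDR set. It fell to 22.8% when 90% of the length had to overlap. Without 1 replicate it ranged from 78.4 to 83.1%, since fewer lists had to match. The pairwise overlap was 79.2% with summits within 100 bp and 50.4% over whole lists, and 81.3 to 84.9% without 1 replicate. The rank agreement was 0.847 over peaks shared by the top lists and 0.808 to 0.839 without 1 replicate. The promoter excess kept its direction and call under all 8 alternatives. The Sox core excess held under 9 settings and reversed under 3. ACAAAG was found near 13.2% of summits, below its flanks. Relative to the median of words with the same bases the ratio was 0.841 (exact rank p = 0.133), and relative to GC-matched windows 0.925. The cause was not tested for ACAAAG. Of the 18 patterns, 5 lay above and 3 below GC-matched windows, in place of 8 and 5. These windows were also matched on promoter status and lay away from all pooled peaks. Which of these differences from the flanks changed the counts was not tested. Occupied genes numbered 5293 within 5 kb and 1585 in the stricter part, which has fewer peaks. There, 1 gene list differed in place of 6. It was 2 to 3 without 1 replicate, where peaks also had to match both others, and 2 with that filter alone. Of the 6 lists, the receptor list differed in 10 of 10 alternatives, the ribosomal list in 9, the wing hinge, gut and testis lists in 4 each and the ecdysone list in 3. The sequencing depth is unknown, so its limits were not assessed. No paired analysis was possible because the series has 1 group.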

Other observations

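The test of GC content over 400 bp and the tests of other sequence words, except that at pooled summits outside the IDR set, were chosen only after the result was seen, and the gene length comparison was planned but read after its value was known. The gene families and the other tests below were chosen after the main results, before their own values. Among the 1856 intronic summits, 1240 (66.8%, 95% interval 64.6 to 68.9%) lay in the first intron of a transcript, where 42.3% were expected from intron length (1.58-fold, binomial test, p = 1.3e-100). This test takes summits as independent, although peaks were clustered, so its p is too small to the extent that they are not. Of small non-coding RNA genes, 10 of 290 tRNA genes (3.45%) and 10 of 269 snoRNA genes (3.72%) had a summit within 500 bp, where random positions on the same arms gave 3.39% and 3.53%. Of 32 snRNA and 99 rRNA genes 0 had one, where 3.79% and 3.45% were expected. These differences were not tested.

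Families of genes expressed in restricted tissues were occupied less often than other genes. Of 118 cuticular protein genes 3 were occupied (2.54%, against 19.4%, Fisher's exact test, adjusted p = 7.12e-07), and of 60 ionotropic receptor genes 1 (adjusted p = 0.000336). Odorant-binding proteins had 1 of 51 (exact test, adjusted p = 0.00196), seminal fluid proteins 1 of 47 (adjusted p = 0.0035), trypsin-like proteases 0 of 27 (adjusted p = 0.0133) and cytochrome P450 enzymes 7 of 85 (adjusted p = 0.0163). The gut list, seen before with 0 of 24 genes occupied, also holds genes of such proteases, so the protease result is not independent of it.

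The ribosomal protein genes stood above the others, and 3 explanations were set against that pattern. Gene length and number of start sites are argued against as the whole cause, since the list was 2.63-fold above lists matched on both (permutation, adjusted p = 0.002). Summits that belong to a neighbouring gene were tested by counting a gene only when its own start site was the nearest and within 250 bp. The ratio was then 5.11-fold, with 37 genes occupied (46.3% against 9.06%, exact p = 6.24e-18), so neighbours are argued against as the whole cause. The rule also narrowed the window, and within 500 bp without it the ratio was 3.29-fold. The size of the rise therefore does not measure the effect of leaving out neighbours. If occupancy followed broadly active promoters in general, housekeeping families would be expected to lie above other genes. The prediction, written before their values were seen, was that at least 4 of 6 would pass the threshold. Of 6 such families, 0 passed the threshold, also at an unadjusted p under 0.05 (Fisher's exact test). By ratio, mitochondrial ribosomal proteins (1.42-fold), vacuolar ATPase subunits (1.26-fold) and translation initiation factors (1.06-fold) lay above other genes. Respiratory complex I (0.907-fold), COX and ATP synthase (0.836-fold) and proteasome subunits (0.431-fold) lay below. Mitochondrial ribosomal proteins had 20 of 73 occupied (27.4%, exact test, adjusted p = 0.15) and proteasome subunits 4 of 48 (8.33%, adjusted p = 0.111). The Wilson upper limits of the 6 families ranged from 19.6 to 41.0%, below the 53.8% of ribosomal protein genes. The prediction was not met. Families this small leave a smaller excess possible, so the test cannot decide whether occupancy followed broadly active promoters. Families of restricted tissues lay below other genes, which goes with that explanation. The DRE lay above its flanks at promoters, but the flanks were not matched on promoter status, so that ratio cannot bear on the explanation. Against windows matched on GC content and promoter status, the DRE was 1.74-fold over all summits (permutation, adjusted p = 0.0036). Differences in transcription level or open chromatin between these genes, and the signal of a control library, stay open. No other biological explanation was tested, since the design has a single group.

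The Sox core lay above its flanks at summits, and base composition is a candidate explanation. Windows elsewhere in the genome, at least 1000 bp from any pooled peak and matched on GC content and promoter status, held AACAAT in 26.6% ± 0.65 (SD over 100 draws), so the share at summits was 0.925 of that, and composition is enough to account for the excess. If the tagged protein were bound at this sequence in most peaks, the word might be concentrated at the summit. Its density within 25 bp over that from 75 to 100 bp was 1.21, and 5 of the 29 other words with the same bases had a lower ratio, with a median of 1.31. This argues against a summit-centred AACAAT as a general feature of the IDR set and does not exclude binding at some of the peaks or at other sequences.

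The near absence of summits from coding sequence was set against GC content. Windows matched on GC content and promoter status lay in coding sequence in 5.82% ± 0.28 (SD over 100 draws) of cases, against 0.373% of summits, so low GC content alone accounts for part of the depletion at most. Recovery of AT-rich fragments over their whole length was tested by the GC content of windows reaching 400 bp to each side. It was 41.6%, against 31.5% within 25 bp and 42.2% over the arms, which does not go with such a bias if fragments were near 800 bp. Windows reaching 100 bp, the size of the shortest fragments, had 34.2%, which goes with it. The lengths of the recovered fragments between 200 and 800 bp are not known, so this explanation stays open. How the peak caller placed summits and whether a control library has the same profile stay open. No biological explanation was tested.

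A hypothesis on other sequence words was tested with the chromosomes split. The ranking of words over all arms had been seen before the split, so chromosomes 3 and X are not independent of the choice. Among words with at least 3 G or C bases, ACACTG had the highest odds on chromosome 2 (17.9% of 1603 summits, 6.61% of flanks). On chromosomes 3 and X it was found near 17.5% of 2942 summits and in 7.78% of flanks, 2.25-fold (exact McNemar test, p = 2.32e-27), against 6.79% ± 0.43 in GC-matched windows. At summits over 500 bp from any start site the ratio was 2.29-fold (exact p = 4.79e-18), which argues against core promoter sequence at annotated start sites as the whole cause. Over all IDR peaks the word was sparse at the summit itself, with a density within 25 bp of 0.365 times that from 75 to 100 bp. Copies 25 to 120 bp away pointed to the summit 486 times and away from it 153 times, a ratio of 3.18, at a median distance of 79.5 bp. The distance range came from the same profile, so no p is given for it. At summits away from start sites the ratio was 5.06, and at promoters 1.82. For ACAGTG, the second word on chromosome 2, it was 3.41 (618 against 181), with 3.71 away from start sites and 2.93 at promoters. These contrasts between promoters and other summits were not tested. The orientation was then tested at 8174 pooled summits outside the IDR set and over 1000 bp from any IDR summit, which had no part in choosing the word or the range. There, copies of ACACTG pointed to the summit 813 times and away 380 times, a ratio of 2.14 (95% interval 1.89 to 2.42, exact binomial test, p = 1.12e-36). For ACAGTG it was 1.91 (783 against 411). These values are consistent with an oriented site beside the summit in a subset of peaks. The orientation test takes copies as independent, although a summit can hold several, so its p may be too small and its interval too narrow. The peaks come from the same libraries, and which protein may recognise the site was not tested.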
